A study of Rattus norvegicus with 5 samples.

How the data were processed

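Dorsal horn of lumbar spinal cord (L4-L6) was taken from Sprague Dawley rats on day 9 after CCI or SHAM surgery, and total RNA was sequenced on an Illumina HiSeq, per the labels. Groups were taken from the treatment label, which gives 3 CCI and 2 SHAM libraries; replicate numbers follow accession order and pair nothing. The authors deposited a table of estimated counts per gene symbol made with kallisto 0.44.0 on the build rn6, per the submitters' processing notes. The authors also deposited a table named TPM, here treated as a signal because its columns do not sum to a fixed total; per the labels it was scaled by trimmed mean of M-values. The gene annotation and any filter of theirs are not given in the sources used here. A gene's estimated counts can be fractional where reads fit more than 1 row, as in 18.6% of tested genes and 15.6% of called genes; such genes are uncertain.

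Estimated counts were rounded to whole numbers. Of 17321 genes in the table, 13478 passed edgeR's filterByExpr (minimum count 10) and were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit with the robust option, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p of at most 0.05 and a fold of at least 1.5, the thresholds the series states. The fit has 3 residual degrees of freedom. The SE is the log2 fold change divided by the root of the F statistic. CPM were computed from TMM-scaled counts. Total counts ran from 20053353 to 23673198 per library, and genes below 1 CPM rest on few counts. Gene lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule names Gpr160 and Cartpt; the 12 largest called changes in each direction with no overlap between groups and a mean CPM of at least 1; up to 4 called members of each list by p, or 2 uncalled members where none was called; and 14 fixed markers. A fixed marker and a gene family are not reported here. Of 31 lists with 797 distinct genes, 29 had at least 5 tested members; 36 genes stand in more than 1 list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using an estimated correlation, and with fry, each adjusted over the 29 lists.

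Scripts were tested on simulated data before use. In simulated CCI against SHAM counts of 13402 genes run, edgeR's quasi-likelihood test called 28.4% of genes changed by 1.5-fold, 83.6% of those changed by 2-fold and 98.5% of those changed by 4-fold, with 15 unchanged genes called. The changed genes all had a mean CPM of at least 1. Genes were drawn independently of each other, so the simulation held no difference in tissue shared by many genes of a library. The alternatives were the likelihood ratio test, DESeq2 1.42.0, limma-voom, other scalings and filters, the deposited TPM table on the log2 scale with pseudocounts of 0.5 and 0.1, and leaving out each library. Alternatives chosen after seeing the data left out ribosomal rows, left out CCI 2 and CCI 3, used the mean level of the Schwann cell list as a covariate, or merged rows that are 1 gene in the GRCr8 gene table. Of the table's rows, 15210 matched that table by symbol and 1747 by a synonym, and 364 did not match; none of its coordinates were used.

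The tests of explanations in the closing section were all written after the values had been seen. First forms of several were replaced. Of these, 4 were Chodl against Chat, Atf3 alone, and the microglia and fibroblast lists in CCI 1 alone. These 4 were replaced because they rested on single genes or on 1 library, and their values were -2.39, 3.74, 1.14 and -0.21 on the log2 scale. By its first form, Atf3 alone would have spoken for a motor neuron response to injury; the whole nerve injury list, used in its place, left that open. An approximate heterogeneity test of 6 motor neuron genes had spoken against a uniform loss of motor neurons. It was replaced by an exact permutation test (p = 0.2), which was then dropped because 10 splits could not have given a p of 0.05. No test kept here weighs a loss of motor neurons. The test of nerve root tissue first took the genes called higher in the fit with the Schwann covariate (median 1.47), and was replaced by lists fixed beforehand because genes picked by the comparison were bound to keep it. It had spoken against nerve root tissue as the whole cause for all of them. Of the 7 immune lists, those of microglia and complement do so by the limits set. That of activated microglia missed those limits, but its intervals exclude 0. A form that pooled the 6 immune lists other than microglia (median 0.714) had left all of them open, and its limits were changed when the lists were taken singly. Limits used in the motor neuron and Mboat7 tests were also changed after the first values were seen. Figures were drawn with matplotlib 3.10.9.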

Results

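RNA was sequenced from the dorsal horn of the lumbar spinal cord (L4-L6), the region that receives sensory input from the hindlimb, of Sprague Dawley rats taken on day 9 after CCI or SHAM surgery. CCI is the usual abbreviation of chronic constriction injury, a nerve ligation used as a model of neuropathic pain, and SHAM is the operation without the injury. There were 3 CCI libraries and 2 SHAM libraries. The series is about the orphan receptor GPR160, so the question here was which genes, Gpr160 among them, differed between the groups. The total estimated count was 21008115, 23673198 and 20724548 in CCI 1, CCI 2 and CCI 3, and 21890192 and 20053353 in SHAM 1 and SHAM 2. Between 14801 and 15039 genes had a count in each library. Ribosomal RNA rows held 16.0% of the counts of CCI 3 and 2.18% to 2.71% of those of the other libraries. The first principal component held 62.5% of the variance and placed CCI 2 at -38.3, CCI 3 at -29.4 and CCI 1 at -1.69, with SHAM 1 at 37.8 and SHAM 2 at 31.7. No pair of libraries was alike within sampling noise. The labels do not say whether each library is from a separate animal, so p-values measure the spread between these libraries.

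Gpr160 was higher after CCI. Its level was 5.93 ± 0.789 CPM, counts scaled to library size (SD, n = 3), in CCI and 1.32 ± 0.316 CPM (SD, n = 2) in SHAM, a log2 fold change of 2.16 (SE 0.28, 4.46-fold, adjusted p = 0.00357). These levels rest on 121, 172 and 101 counts in the CCI libraries and on 34 and 22 counts in the SHAM libraries. A two-sided exact permutation test of the log2 CPM gave p = 0.1, the smallest value that the 10 splits of these 5 libraries allow. The Gpr160 call was lost when either SHAM library was left out, with an adjusted p of 0.055 without SHAM 1 and 0.078 without SHAM 2. Cartpt, which encodes the CART peptide, was 7.95 ± 1.25 CPM (SD, n = 3) in CCI and 10.3 ± 2.57 CPM (SD, n = 2) in SHAM, a difference that did not pass the test (log2 fold change -0.37, SE 0.21, adjusted p = 0.439).

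**Figure D1:**
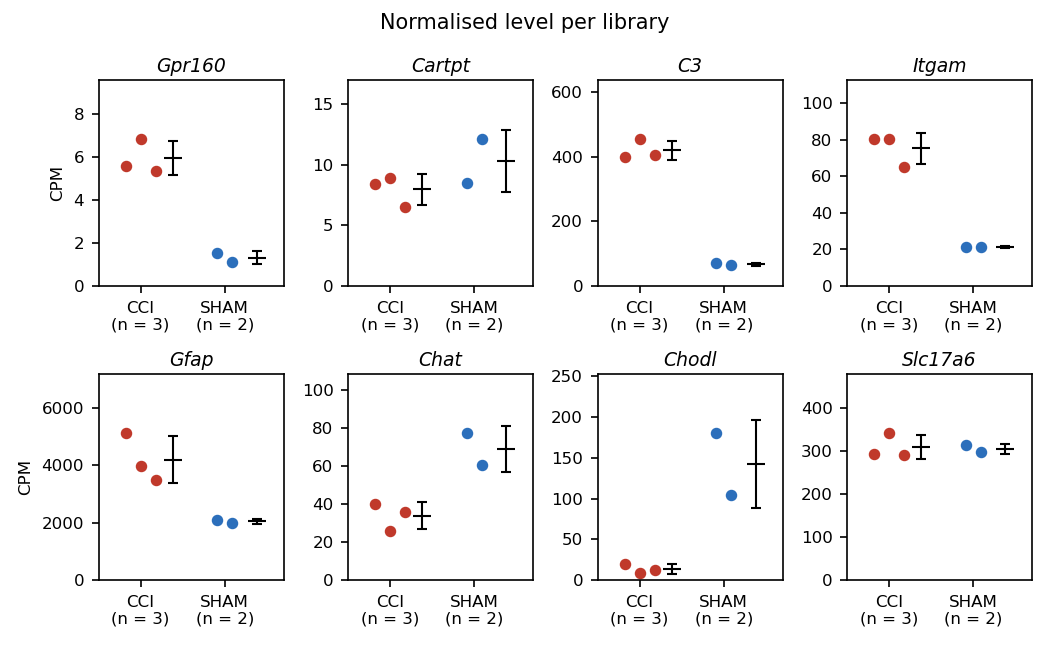
Normalised level (CPM, linear axis from 0) of 8 named genes in each library; dots are libraries, and the black bar with whiskers is the group mean ± SD. Gpr160 was 5.93 ± 0.789 CPM in the 3 CCI libraries and 1.32 ± 0.316 CPM in the 2 SHAM libraries, while Slc17a6 was 309 ± 28.5 CPM and 305 ± 11.5 CPM.

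Several genes known from immune cells were among the 12 largest increases picked by the rule. They included Cxcl13, a chemokine that attracts B cells (log2 fold change 6.19, SE 0.37), Clec7a, the receptor for fungal beta-glucan (5.87, SE 0.31), Plac8 (5.21, SE 0.43), Clec12a (4.20, SE 0.32) and Tlr8, an endosomal sensor of RNA (4.11, SE 0.48). Cxcl13 and Clec7a were at 0.216 ± 0.0481 CPM and 0.189 ± 0.0547 CPM (SD, n = 2) in SHAM, so their folds rest on few counts. Csf2rb, a shared receptor chain for GM-CSF, rose by 3.87 (SE 0.21), Aoah by 3.78 (SE 0.45), Tfec by 3.73 (SE 0.50), Clec4a3 by 3.63 (SE 0.29) and Gpr65 by 3.52 (SE 0.54). In SHAM 1 and SHAM 2, Gpr65 had 3 and 3 counts, Tfec 9 and 2, Aoah 12 and 4 and Tlr8 11 and 8, so these folds also rest on few counts. The complement gene C4a rose by 3.46 (3.49, SE 0.22, adjusted p = 0.00037, when its counts were summed with those of C4b, a sum chosen after the values were seen). Mboat7 had a log2 fold change of 6.08 (SE 0.55) and is uncertain, since the row Mboat7l1 moved the other way. Mboat7 stood at 77.7, 41.4 and 47.0 CPM in CCI 1 to 3 and at 0.409 and 1.25 CPM in SHAM, while Mboat7l1 stood at 0.833, 34.3, 40.6, 60.8 and 71.8 CPM in the same order. Unless another test is named, calls here and below are from edgeR's quasi-likelihood test. In total 384 of 13478 tested genes passed an adjusted p of 0.05 with a fold of at least 1.5, of which 349 were higher and 35 lower in CCI. The count depended on single libraries: it was 61 without SHAM 1, 78 without SHAM 2 and 763 without CCI 1.

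Microglial genes rose together. Of 28 tested members of the microglia list, 20 rose and none fell (21 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.20. The subunits of C1q, which starts the classical complement pathway, were C1qa at 2.36 (SE 0.12), C1qb at 2.59 (SE 0.13) and C1qc at 2.82 (SE 0.18). Itgam, a surface integrin of microglia, rose by 1.82, Csf1r by 1.64, Cx3cr1 by 1.21 and Aif1 by 2.03. The list passed camera with its preset correlation (adjusted p = 1.85e-26) and not with an estimated correlation (adjusted p = 0.149). Of 30 genes of activated microglia and phagocytes, 16 rose (19 when adjusted over the list alone), among them Fcgr2b at 2.47, Gpnmb at 1.75 and Tlr2 at 1.87, while P2rx4 had a log2 fold change of 0.00 (SE 0.20, adjusted p = 0.994). That list had a camera adjusted p of 6.94e-17, and an adjusted p of 0.149 with an estimated correlation. In the complement list 9 of 22 tested genes rose (16 when adjusted over the list alone), among them C3, the central complement protein, at 2.64 (SE 0.12). Its camera adjusted p was 3.24e-18, and its adjusted p with an estimated correlation was 0.0941. Without SHAM 1 the number called was 8 in the microglia list, 4 in the activated list and 7 in the complement list; without SHAM 2 it was 11, 5 and 6. In the complement list it was 15 without CCI 1, 14 without CCI 2, 14 with the likelihood ratio test and 15 with DESeq2.

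Several genes of reactive astrocytes rose. In the reactive list 10 of 27 genes rose (14 when adjusted over the list alone) with a median log2 fold change of 1.46, a camera adjusted p of 3.99e-12 and an adjusted p of 0.0941 with an estimated correlation. Lcn2, a secreted iron-binding protein, rose by 3.03 (SE 0.26), Timp1 by 2.44, the intermediate filament gene Vim by 2.01 and Cd44 by 1.08. Gfap, the main astrocyte filament, was 4191 ± 831 CPM (SD, n = 3) in CCI and 2041 ± 83.9 CPM (SD, n = 2) in SHAM, a log2 fold change of 1.04 (adjusted p = 0.0138). Of 19 general astrocyte genes 1 fell, the amino acid transporter gene Slc7a10 (-0.76, SE 0.13), with a list camera adjusted p of 0.0293 and an adjusted p of 0.453 with an estimated correlation. The Slc7a10 call was lost with the Schwann cell list as a covariate. Among cytokines, chemokines and their receptors, 7 of 27 genes rose (10 when adjusted over the list alone), including Cxcl16 at 1.65, Tnfrsf1a at 1.07 and Tnfrsf1b at 1.58. That list had a camera adjusted p of 4.13e-09, and an adjusted p of 0.149 with an estimated correlation. Without SHAM 1 and without SHAM 2, 2 and 3 reactive astrocyte genes and 1 and 1 cytokine genes were called.

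Of 62 tested orphan or recently paired G protein-coupled receptors, 6 rose and none fell, the same counts as when adjusted over the list alone. They were Gpr160, Gpr183, Gpr34, Gpr31, Gpr65 and Gpr84, with log2 fold changes of 1.69 (SE 0.21) for Gpr183, 0.94 (SE 0.13) for Gpr34 and 1.61 for Gpr84, which was named because it completes the set. Gpr31 was 3.91 ± 0.663 CPM (SD, n = 3) in CCI and 0.975 ± 0.0359 CPM (SD, n = 2) in SHAM. Gpr160 ranked 2 of the 62 by p, 3 by log2 fold change, and 113 of all 13478 genes by p. The list as a whole did not pass camera (adjusted p = 0.176), and none of its genes was called when either SHAM library was left out.

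Several genes of motor neurons fell. In the list of motor and ventral horn neurons 5 of 20 genes fell and none rose (7 lower when adjusted over the list alone). Chodl, a gene of fast motor neurons, fell by 3.41 (SE 0.45), the motor neuron transcription factor gene Mnx1 by 2.71, the choline transporter gene Slc5a7 by 1.96, Lhx4 by 1.83 and Chat, the enzyme that makes acetylcholine, by 1.02. The list's median log2 fold change was -0.78, its camera adjusted p was 1.31e-07, and its adjusted p with an estimated correlation was 0.403. Outside the list the decreases picked by size were Musk (-2.08), Trim58 (-1.73), Stk32a (-1.52), Kcnj14 (-1.30), Pla2g3 (-1.26) and the neurofilament genes Nefm (-1.42), Nefl (-1.30) and Nefh (-1.23). Chodl, Chat, Kcnj14 and Slc7a10, like C1qb, Fcgr2b and Cx3cr1 among the higher genes, had fractional estimated counts that can share reads with other rows, and are uncertain. No gene of the motor list was called when either SHAM library was left out or with the Schwann cell list as a covariate; the list median was -0.28 without SHAM 1, -0.78 without SHAM 2 and -0.44 with the covariate. With CCI 2 and CCI 3 left out it was -0.37. Without CCI 3, 2 genes of the list were called lower, and 7 were without CCI 1, with the likelihood ratio test and with DESeq2.

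**Figure D2:**
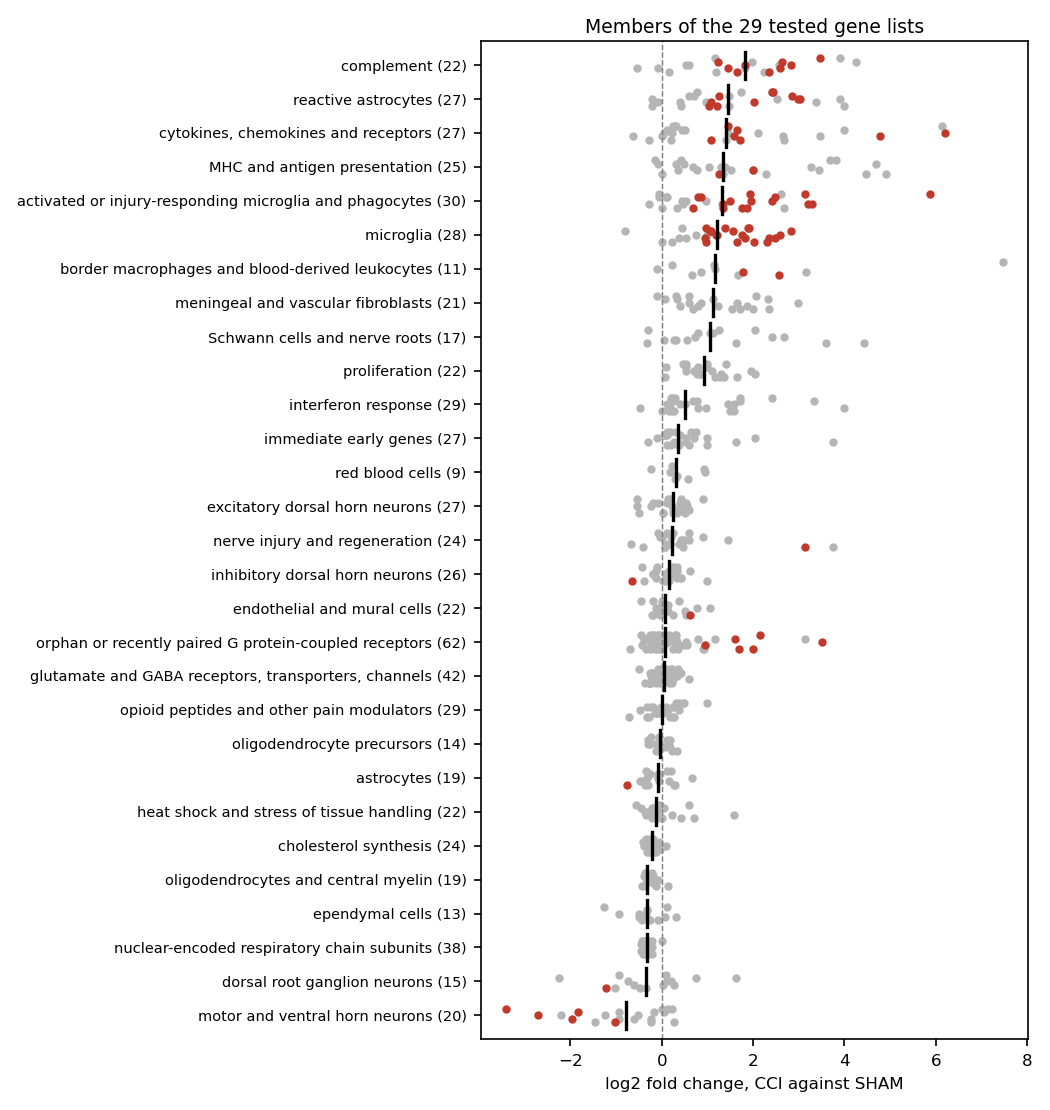
Log2 fold change (CCI against SHAM, horizontal axis) of each tested member of the 29 tested gene lists, with the number of tested members in brackets; red dots passed the test, grey dots did not, and the black bar is the list median. The medians run from -0.78 for motor and ventral horn neurons to 1.82 for complement.

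Few genes of dorsal horn neurons passed the test. None of 27 excitatory genes passed (Cck -0.50, Car12 -0.54, Slc17a6 0.02; camera adjusted p = 0.0915), and 1 of 26 inhibitory genes fell, the calcium-binding protein gene Pvalb (-0.65, SE 0.14; list camera adjusted p = 0.664), with Gad1 at 0.07. That call was lost without CCI 2, CCI 3, SHAM 1 or SHAM 2. Adjusted over the inhibitory list alone 1 gene was higher and 1 lower, as with the likelihood ratio test and DESeq2 over all genes. None of 42 glutamate and GABA receptor, transporter and channel genes passed (Cacna2d1 0.59, Kcna1 -0.49, Slc12a5 -0.02; camera adjusted p = 0.846, direction down although the median was 0.05), while the likelihood ratio test, and the main test without a low-count filter, each called 1 higher. None of 29 genes of opioid and other pain modulators passed (1 higher and 1 lower when adjusted over the list alone, with the likelihood ratio test and with DESeq2; Chrm2 -0.48, Htr2a -0.71; camera adjusted p = 0.881). In the list of dorsal root ganglion neurons 1 of 15 fell, Nefh, with a camera adjusted p of 0.0143 and an adjusted p of 0.403 with an estimated correlation. The number of these called lower was 3 without CCI 1, without CCI 2, with the likelihood ratio test and with DESeq2, and 0 without CCI 3 or either SHAM library. Of 24 nerve injury genes 1 rose (3 when adjusted over the list alone), Reg3b (3.13, SE 0.59), with a camera adjusted p of 0.00798 and an adjusted p of 0.403 with an estimated correlation. No nerve injury gene was called without CCI 3, with limma-voom or with the Schwann cell list as a covariate. Without CCI 1, 3 were called higher and 1 lower, and without CCI 2, 3 were called higher. None of 27 immediate early genes passed (Atf3 3.74, SE 0.66, adjusted p = 0.0542; Pim1 0.99; Fos 0.59; Bdnf 0.30), and their camera adjusted p of 6.75e-05 became 0.403 with an estimated correlation. Of these 27, 3 were higher when adjusted over the list alone, and the likelihood ratio test and DESeq2 each called 3 higher over all genes. No immediate early or nerve injury gene was called when either SHAM library was left out.

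Schwann cell and fibroblast genes varied widely between the CCI libraries, and none was called in the main fit of all 5 libraries; the likelihood ratio test and DESeq2 each called 1 fibroblast gene higher and no Schwann cell gene. Without CCI 1, 5 of 17 Schwann cell genes and 12 of 21 fibroblast genes were called higher. The Schwann cell median was 0.49 without CCI 3, over 15 tested genes rather than 17. The mean log2(CPM + 1) of the Schwann cell list was 2.97, 3.84 and 4.40 in CCI 1 to 3 and 2.80 and 3.08 in SHAM 1 and 2. Col3a1, a collagen gene named after its values were seen, was 19.3, 417 and 265 CPM in CCI and 22.2 and 36.8 CPM in SHAM. None of 17 Schwann cell genes passed (Pmp2 1.12, Ngfr 0.79), with a median of 1.05, a camera adjusted p of 0.012 and an adjusted p of 0.462 with an estimated correlation. None of 21 fibroblast genes passed the main test (Foxc2 1.53; Aldh1a2 10.8 against 2.70 CPM), with a median of 1.13, a camera adjusted p of 0.000369 and an adjusted p of 0.537 with an estimated correlation. Of 29 genes of border macrophages and blood leukocytes in the table, only 11 had enough counts to be tested. Of these 2 rose (3 when adjusted over the list alone), Cd4 (2.57, SE 0.13) and Cd6 (1.77). The list had a camera adjusted p of 4.59e-05 and an adjusted p of 0.403 with an estimated correlation. In the antigen presentation list 2 of 25 rose (4 when adjusted over the list alone), RT1-DMa (33.7 against 14.2 CPM) and RT1-DMb (28.7 against 7.20 CPM), with a camera adjusted p of 1.56e-07 and an adjusted p of 0.405 with an estimated correlation. The number of antigen presentation genes called was 0 without SHAM 1, without SHAM 2 and with the Schwann cell list as a covariate, 8 without CCI 1, 7 without CCI 2, 10 with the likelihood ratio test and 11 with DESeq2; with the covariate their median was 1.11. Without CCI 2 the median fell from 1.34 to 0.89 in the antigen presentation list and from 1.17 to 0.56 in that of border macrophages and leukocytes. Fewer genes were tested there, 24 against 25 and 8 against 11, so the medians compared are not of the same genes. With CCI 2 and CCI 3 left out, which leaves a single CCI library and a spread taken from SHAM alone, 406 genes passed and 290 of them were among the 384. With the Schwann cell list as a covariate 173 passed, 165 of them among the 384, and all 173 were higher.

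**Figure D3:**
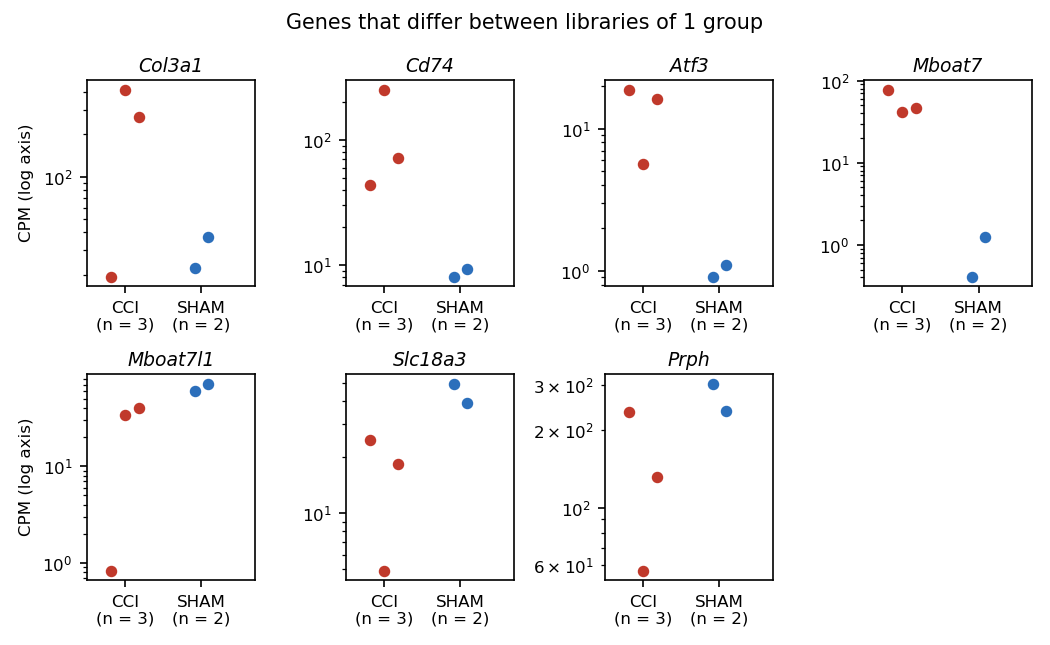
CPM (log axis) of 7 genes, picked after their values were seen, in each library; dots are libraries. Col3a1 was 19.3 CPM in CCI 1, 417 CPM in CCI 2 and 265 CPM in CCI 3, and Mboat7l1 was 0.833 CPM in CCI 1 against 60.8 and 71.8 CPM in SHAM.

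The remaining lists held 1 call of the main test among them, Pltp (0.62, SE 0.13) of 22 endothelial and mural genes, whose list did not pass (camera adjusted p = 0.439). That call was lost without CCI 3 and with the Schwann cell list as a covariate. Pltp also had fractional estimated counts and is uncertain. Lists that passed camera with no member called were myelin (median -0.32, adjusted p = 1.65e-07; Ermn -0.38, Mal -0.39), respiratory chain subunits (-0.33, adjusted p = 3.95e-15; Uqcrh -0.46, Ndufc2 -0.37), cholesterol synthesis (-0.22, adjusted p = 3.13e-06; Mvk -0.41, Hmgcs1 -0.32), proliferation (0.92, and 0.38 without CCI 2, adjusted p = 6.33e-05; Mcm3 1.36, Mcm6 0.70) and interferon response (0.50, adjusted p = 1.86e-06; Ifitm3 1.72, Ifih1 0.77). With an estimated correlation their adjusted p was 0.403 for myelin, the respiratory chain and interferon, 0.405 for cholesterol synthesis and 0.462 for proliferation. Adjusted over the list alone, 6 interferon genes were higher and none of the other 4 lists had a call. The likelihood ratio test and DESeq2 each called 7 interferon genes higher over all genes. The main test called 5 of them higher without CCI 1 and 5 without CCI 2, but none without CCI 3. Ependymal genes (median -0.32, camera adjusted p = 0.0169; Cfap126 -0.49, Foxj1 -0.43) and heat shock genes (median -0.12, mean 0.00, camera adjusted p = 0.0491; Tsc22d3 -0.57, Mt2A 1.59) had adjusted p of 0.453 and 0.403 with an estimated correlation. The ependymal median was -0.58 without CCI 1, with 3 genes called lower, and -0.04 without CCI 3; 2 heat shock genes were higher when adjusted over the list alone. The likelihood ratio test and DESeq2 each called 1 proliferation and 1 heat shock gene higher, and DESeq2 called 2 endothelial and mural genes. Without CCI 3, 4 proliferation genes were called higher. Oligodendrocyte precursor genes (Olig1 -0.29, Gpr17 -0.26; camera adjusted p = 0.466) and red blood cell genes (Epb42 0.32, Slc4a1 0.28; camera adjusted p = 0.439) did not pass. Of the sex-linked genes, Usp9y was 150 ± 39.8 CPM (SD, n = 3) in CCI and 134 ± 12.01 CPM (SD, n = 2) in SHAM, and Sry was 0.922 ± 0.284 CPM and 0.745 ± 0.218 CPM. Of the 29 lists, 21 passed camera with the preset correlation, none with an estimated correlation and 4 passed fry (microglia, activated microglia, reactive astrocytes and complement).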

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

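Leaving out ribosomal rows, CCI 2 with CCI 3, the Schwann covariate and merging rows were chosen after seeing the data. All 384 calls, where tested, kept their direction under each alternative that refitted the genes (not counted for merged rows). Leaving out a library could hardly have turned a direction, since all 384, Gpr160 among them, had no overlap between groups (36.7% of tested genes had none). The number of calls did not hold. It was 646 with the likelihood ratio test, 606 with DESeq2, 173 with the Schwann covariate and 10 with the unfiltered deposited TPM; leaving out 1 library each gave 61 to 763. Without SHAM 1 (61 calls) or SHAM 2 (78), SHAM is a single library assumed to vary like the CCI libraries; without CCI 1 it was 763. Merging rows of 1 gene gave 382. The Gpr160 log2 fold change was positive throughout, from 1.93 to 2.43 when 1 library was left out; its call was lost without SHAM 1 (2.43, adjusted p = 0.055), without SHAM 2 (1.93, adjusted p = 0.078) and in the unfiltered TPM (1.79, adjusted p = 0.101). Of the gene lists, 21 passed camera, 0 with an estimated correlation (16 to 21 under other scalings, filters and left-out libraries) and 4 with fry. With CCI 2 and CCI 3 left out, which leaves 1 CCI library and takes the spread from SHAM alone, the fibroblast list turned down (adjusted p = 0.0458) and the ependymal list up (adjusted p = 0.484); the cause was not tested. Except for the fewer libraries or the unfiltered genes named here, the cause of the other changes was not tested. With Gpr160 at 22 to 34 counts in SHAM, its fold is set by few counts.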

Other observations

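All tests in this part were chosen after the results were seen. Gene families were formed from the letters that open a symbol, and 445 families with at least 5 tested members were tested for calls higher in CCI with a one-sided Fisher's exact test. After adjustment 6 families passed and none did for lower calls. Of 10 tested Toll-like receptor genes, 6 rose (Tlr1, Tlr2, Tlr4, Tlr7, Tlr8 and Tlr9; adjusted p = 1.24e-05), with Tlr1 at a log2 fold change of 2.68 and Tlr4 at 1.33. Of 16 C-type lectin genes, 6 rose (adjusted p = 0.000241), and of 5 genes named for colony stimulating factors 4 rose, all of them receptors (Csf1r, Csf2ra, Csf2rb and Csf3r; adjusted p = 0.000241). Of 43 interleukin-named genes 8 rose (adjusted p = 0.00109); 7 are receptor genes, among them Il21r (2.03), Il1r1 (1.45) and Il6r (1.26), and the other is Il16. The Cd family had 17 of 59 higher and Cd24 lower (adjusted p = 3.3e-11). These names group genes by nomenclature, and genes of 1 cell type are not independent.

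Motor neuron genes were lower in CCI. The median of 11 of them, a set picked after the values were seen, was also below 0 without SHAM 1 (-1.51) and without SHAM 2 (-2.10). The motor list fixed beforehand had a median of -0.78 in all libraries, -0.28 without SHAM 1 and -0.78 without SHAM 2. Less ventral horn tissue in the CCI samples is argued against, only weakly, by 8 tested genes of ventral interneurons. Of these, 5 also stand in the motor list. Their median log2 fold change was -0.0921 (bootstrap 95% interval over genes -0.85 to 0.17), above that of the 11 motor neuron genes (-1.83, interval -2.25 to -1.02). These intervals treat genes as independent, which genes of 1 cell type are not, and do not measure the spread between libraries. Both sets were picked after the values were seen, so part of the gap may come from the choice of genes. In addition, 3 of the 8 were low in counts, and the intervals overlapped without SHAM 2 (-1.36 to 0.11 against -2.56 to -1.20). In SHAM 1, 7 of the 8 ventral interneuron genes and 10 of the 11 motor neuron genes were above SHAM 2, with median ratios of 1.30 and 1.27, so the share of ventral tissue may differ between libraries and account for part of the fall. A loss of motor neurons stays open. The permutation test of it was dropped, since the 10 splits of these libraries cannot give a p below 0.1. The approximate test that it had replaced had spoken against a uniform loss, but it was not kept and no conclusion is drawn from it. A response of motor neurons to the nerve injury stays open. The nerve injury list fixed beforehand had a median of 0.23 (interval 0.09 to 0.46), above 0 but below the fold threshold. That list also holds genes of the dorsal horn neuron lists, such as Npy and Nts, so its median cannot single out motor neurons.

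Microglial and immune genes were higher in CCI, and CCI 2 and CCI 3 also carried more Schwann cell RNA. Nerve root tissue as the whole cause is argued against for the microglia and complement lists, both fixed beforehand, by the fit with the Schwann cell list as a covariate. The median log2 fold change of the microglia list was 1.17 (bootstrap 95% interval over genes 0.98 to 1.69) against 1.20 without the covariate, and that of the complement list 1.49 (0.87 to 2.33) against 1.82, while that of the fibroblast list moved from 1.13 to 0.02. Genes of 1 cell type are not independent. With the list mean as a single value per library, the difference between groups had a 95% interval of 0.27 to 1.97 for microglia and 0.18 to 2.51 for complement, which excludes 0 but not a difference below the fold threshold. For the 18 complement genes outside the microglia list the median was 1.14 (0.67 to 1.89), and the interval over libraries, -0.24 to 2.45, included 0. For activated microglia the median was 0.912 (interval 0.54 to 1.83, and 0.29 to 1.87 over libraries, against 1.32 without the covariate). By the limits set, this list was left open, since the interval over genes reached below the fold threshold. Both intervals exclude 0, which argues only weakly against root tissue as the whole cause for this list. That reading uses a looser rule, taken after the values were seen. Root tissue as the whole cause stays open for the other 4 immune lists. Their medians were 1.11 for antigen presentation (0.52 to 2.12, against 1.34), 0.652 for cytokines and chemokines (0.29 to 1.32, against 1.41), 0.492 for border macrophages and leukocytes (-0.10 to 2.19, against 1.17) and 0.388 for the interferon response (0.18 to 0.79, against 0.50). In each of these 4 the interval over genes reached below the fold threshold and that over libraries included 0. With the covariate 165 of the 349 genes called higher were still called, with 2 residual degrees of freedom, so the loss of calls is also one of precision. Root or meningeal tissue may still add to part of the pattern, and the injury itself, which the design names, stays open.

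The increase of Mboat7 may come from how rows are defined. The GRCr8 gene table lists Mboat7l1 as another name of Mboat7, and the summed row had a log2 fold change of 0.26 (SE 0.12, adjusted p = 0.326), so reads of like sequence that went to either of 2 rows are a candidate explanation. Mboat7 held 98.9% of the sum in CCI 1, 54.7% in CCI 2, 53.7% in CCI 3, 0.668% in SHAM 1 and 1.71% in SHAM 2, at most 4.7 points from 0, 50 or 100%, a pattern that a sequence variant carried by some of these outbred rats could give; reads would be needed to test it. Of the 384 calls, 3 share a GRCr8 gene with another row, and none of the 3 was called after merging: Mboat7, and Lilrb3a and Lilrb3b, which merged with Pirb to 2.16 (SE 0.45, adjusted p = 0.0564).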
